A study of Halobacterium salinarum NRC-1 with 20 samples.

How the data were processed

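RNA of Halobacterium salinarum NRC-1, a halophilic archaeon, was measured on Agilent tiling arrays with 62976 spots. The set held 40 arrays on 5 slides. A strain from which ura3 had been deleted was grown in 19 cultures over 10 media, and each culture was set against 1 common reference RNA of wild type cells. Each RNA was hybridised in both dye orientations. The RNA of M2 replicate 1 was hybridised as 2 technical replicates, which gave 20 hybridised samples. Groups were the media of the labels: M12 had 1 culture, and the other 9 media had 2 each.

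The deposited scanner files hold signal intensities per the file headers, written by Agilent Feature Extraction 10.7.3.1. Their LogRatio column is, per the file headers, the log10 ratio of red to green after the scanner software's background subtraction and dye normalisation. The deposited values of the series are, per the labels, the log10 ratio of culture to reference averaged over the dye swap by the authors; the other steps behind it are not stated.

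The mean signals were background corrected with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 on R 4.3.3, with the packages statmod (1.5.0) and data.table (1.17.8). Spots marked by the scanner software as non-uniform were left out. Log2 ratios were oriented as culture over reference from the dye labels. No genome sequence was at hand. The sequences of the overlapping probes and their positions were therefore joined into 2570958 bases, which left no base uncovered and no overlap in conflict, and all coordinates given here are those of the array. BLAST+ 2.17.0 searched each probe against these bases. A probe with a second place of at least 50 bases at 90% identity or more was left out, except in 319 genes that had no other probes. Of 26480 probes inside a gene on its strand, 26273 were used. The value of a gene on an array was the median of its probes. The arrays of a culture were averaged, so that a culture was 1 value.

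The platform names loci by identifier. A reference list of genes gave symbols for 364 of 2597 genes but no product text. Its genes were placed on the array by the exact length and the order of open reading frames. A match needed at least 6 of the neighbours, out of 10 looked at on each side, to share its offset within 60 bases. This matched 1854 loci, 322 of them with a symbol. The same search with shuffled gene lengths matched 0 genes. Gene bop was placed by a peptide of 61 residues. Genes kdpA, kdpB and csg were placed by protein motifs in the joined sequence, a search added after expression values had been seen. Since no product text was at hand, the parts of the gene lists and of the naming rule that search product text were not applied.

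Of 2674 loci, genes with at least 3 probes, and with over 50% of them well above background in the culture channel on at least 2 arrays, were tested, which left 2436. Of the tested genes, 318 had a symbol, 494 lay on the large plasmids pNRC100 and pNRC200, and 293 had repeated probes alone, so that their values are uncertain as to locus. limma fitted 1 mean per medium to the 19 cultures, with empirical Bayes moderation, 9 residual degrees of freedom and 3.76 prior degrees of freedom. M12 was assumed to vary like the other media. P values were adjusted over genes by the method of Benjamini and Hochberg, within each comparison, at a false discovery rate of 0.05. The comparisons were a moderated F test over media, NaCl levels as means of their media, slopes over the KCl share (KCl as a part of KCl plus MgSO4, from 0 to 1) at each NaCl level, the difference of slopes between 2.57 M and 4.28 M, MgSO4-free media (M5 minus M2 and M15 minus M14, averaged), KCl-free media (M1 minus M2 and M6 minus M7, averaged), the interactions of both with NaCl, and each medium against M2. The 9 comparisons with M2 share its 2 cultures, so their overlap was set against 100 simulations with no change in any medium and against the number that independent calls would share. Tested on simulated data with a change of 2 (log2) in M9 alone, the F test recovered 189 of 200 changed genes with 9 false calls. A change of 1 (log2) was recovered in 97% of simulated genes for 2.57 M against 4.28 M, 91% for 3.42 M against 4.28 M, 95.5% for MgSO4-free media and 94% for KCl-free media. The same change was recovered in 41.8% at 2.57 M, 46.3% at 3.42 M and 82.1% at 4.28 M for the KCl slopes, and in 10.4% for their difference. For a medium against M2 the share lay between 59.7% and 82.1%. False calls made up 0.8% to 6.5% of calls. The simulated noise was independent between genes and cultures. In the data, the differences between replicates correlated across genes between pairs of media at -0.803 to 0.94. The simulated rates therefore need not hold for the data.

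The genes named were, for each comparison, the 8 largest rises and 8 largest falls with a symbol past the threshold (3 and 3 for a medium against M2), the strongest member past the threshold of each list called, and always ura3, bop, hop, gvpA, kdpA, arcA and csg; dmsA had no symbol in the reference and was not measured by name. The comparisons, this rule, the gene lists and most alternatives were set before the data were examined. The lists fixed then were retinal proteins and carotenoids, gas vesicles, phosphate transport, motility and chemotaxis, ribosomal proteins, respiratory chain and tricarboxylic acid cycle, chaperones and proteases, cobalamin synthesis, pyrimidine synthesis and genes on the large plasmids. Arginine fermentation, dimethyl sulfoxide respiration, potassium transport, iron, sulfur and cell surface had fewer than 5 members with a symbol and were not tested as lists. Sodium antiport, divalent metal transport, amino acid uptake, general transcription factors, ATP synthase, transposases and compatible solutes had none. Purine synthesis, aminoacyl-tRNA synthetases, aromatic amino acid synthesis, histidine synthesis, amino acid catabolism, DNA replication and repair, oxidative stress defence, tetrapyrrole synthesis and glycolysis were added once the symbols were known, before any expression result. Lists were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry.

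The alternatives were no background correction, Agilent's log ratios, the authors' values, between-array quantile normalisation, median centring, the mean of probes, at least 1 probe, no filter, a stricter filter, a replicate block, scan batch as a block or each batch alone, slide as a block, technical replicate 2 left out, only the media compared, M12 left out, a trended robust prior, culture density as a covariate, a rate of 0.01, media matched in KCl share, and each culture left out in turn. Chosen after seeing the data were the opposite-strand signal as a covariate, the median of tiling probes outside annotated gene strands subtracted from each channel, the 9 cultures with a high opposite-strand signal left out, arrays as single values without batch or slide, and each medium of a pair set against its own culture of M2. The opposite-strand signal was the median of 20815 probes that lie on the strand opposite a gene, over the median of 308 negative control spots. Plots and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene symbols outside the reference list and RNA genes without a match were left without a name.

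Between 60.6% and 99.4% of all probes other than controls lay well above background in the culture channel of an array. In the reference channel the share was 55.5% to 92.6%, and none was saturated. These probes include those outside gene strands, so the share does not measure the detection of genes alone. It was highest on an array of M14 replicate 1, the culture with the highest opposite-strand signal. The number of cultures limits the precision, since the arrays of a culture were averaged. Across genes, the dye-swapped arrays of a culture correlated at 0.744 to 0.961 and the replicates of a medium at 0.548 to 0.942. The values of a culture correlated with the authors' values at 0.879 to 0.988. Genes are not independent replicates.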

Results

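Transcripts of Halobacterium salinarum NRC-1, an archaeon that grows in concentrated brine, were measured in 19 cultures of a strain without ura3. The cultures grew in 10 media that held the same total salinity of 4.388 M but differed in the mix of NaCl, MgSO4 and KCl. Media M1, M2 and M5 held 4.28 M NaCl (6 cultures), M6, M7 and M9 held 3.42 M (6 cultures), and M12, M13, M14 and M15 held 2.57 M (7 cultures). At each NaCl level KCl replaced MgSO4. KCl made up none of this remainder in M1 and M6, 0.25 in M2, M7 and M12, 0.5 in M13, 0.75 in M9 and M14, and all of it in M5 and M15. M2 was the standard medium. Each medium had 2 cultures except M12, which had 1. Per the labels, the cultures grew at 37 °C and were harvested at an optical density of 0.408 to 0.545. Each was compared on dye-swapped arrays with 1 reference RNA from wild type cells in standard medium at an optical density of 0.471. Values are log2 ratios of culture to reference or differences between them, with the standard error (SE) of the fit in limma. The number of cultures, 1 or 2 in a medium, limits their precision, since the dye-swapped arrays of a culture are averaged, and the median residual SD of a gene between cultures of a medium was 0.182.

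The deleted gene served as a check of labels and dye orientation. Gene ura3 (VNG1673G, with the symbol pyrF in the reference, chromosome, 1246393 to 1247124) encodes the orotidine monophosphate decarboxylase of pyrimidine synthesis. It was below the reference in 19 of 19 cultures and on 40 of 40 arrays, with a median of -1.30 over cultures and a range of -2.32 to -0.69. The median was -1.60 with Agilent's log ratios and -0.98 with the authors' values. All 9 probes inside the gene were used, since the ends of the deletion are not known.

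The scans fell into 2 batches. All cultures of replicate 2 were scanned in batch 1, and those of replicate 1 in batch 2, except M6 replicate 1 (batch 1) and M2 replicate 1 (both). Replicate numbers did not pair the cultures, so batch was examined through blocked fits and values within each batch. Probes on the strand opposite to genes also differed between cultures: their median lay between 1.35 (M7 replicate 1) and 3.00 (M14 replicate 1) above the control spots. The mean of this signal was 2.21 ± 0.49 (SD, n = 7 cultures) at 2.57 M NaCl, 1.65 ± 0.27 (SD, n = 6) at 3.42 M and 1.75 ± 0.42 (SD, n = 6) at 4.28 M. The difference of 0.46 between 2.57 M and 4.28 M did not pass an exact permutation test (2-sided p = 0.0985). It was 2.02 against 1.94 in batch 1 and 2.46 against 1.37 in batch 2. Fits with this signal as a covariate, and fits without the 9 cultures in which it exceeded 1.8, were chosen after seeing the data. The first principal component, the main axis of variation of the gene values between cultures, held 38.8% of their variance. It was negative in those 9 cultures and positive in all others. Replicates 2 and 1 lay on opposite sides in M1 (-8.59 and 14.15), M5 (-16.08 and 6.80) and M7 (-0.68 and 7.54). In the other media with 2 cultures both lay on the same side. The cause of this split was not tested.

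**Figure D1:**
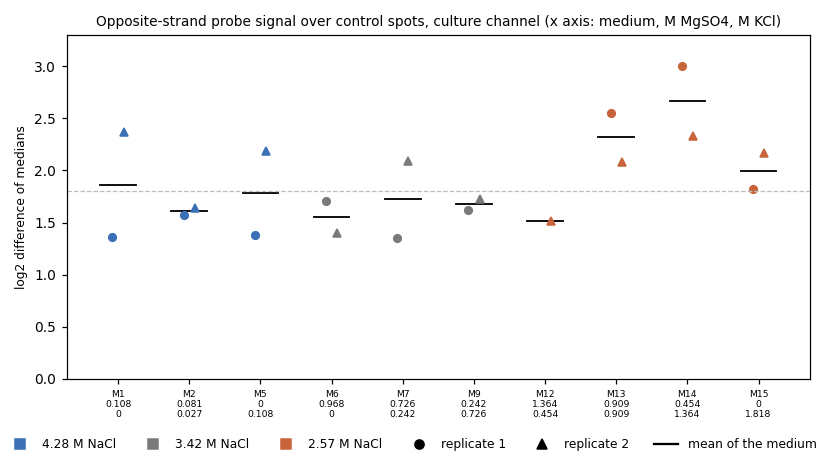
Median signal of opposite-strand probes over control spots (log2) in each culture, by medium. The dashed line marks 1.8, which 9 cultures exceeded, with M14 replicate 1 highest at 3.00.

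Which genes respond to ion composition at a constant total salinity was asked first over all media. Transcripts of the potassium pump subunits kdpB (VNG6177G, pNRC200, 149269 to 151344, plus strand) and kdpA (VNG6176G, pNRC200, 147505 to 149244, plus strand) varied among the media, with F test adjusted p of 4.4e-07 and 9.47e-07. In the media without added KCl, kdpB stood at 5.14 ± 0.14 in M1 and 4.79 ± 0.62 in M6 (SD, n = 2 cultures each), and its means in the other 8 media lay between 0.04 and 0.43. Bacterio-opsin, the protein of the light-driven proton pump (bop, VNG1467G, chromosome, 1089145 to 1089876, plus strand), ranged from -0.03 in M2 to 3.85 in M12, with its 1 culture (adjusted p = 0.0105). The cobalamin synthesis gene cbiT (VNG1550G, chromosome, 1156933 to 1157412, plus strand) ranged from -2.29 in M6 to 0.35 in M5 (adjusted p = 8.71e-06). The catalase-peroxidase gene katG (VNG6294G, pNRC200, 224995 to 227154, minus strand) ranged from 0.23 in M15 to 2.42 in M12, again in 1 culture (adjusted p = 0.000928). The F test in limma passed 532 of 2436 genes, and 939 had an unadjusted p under 0.05. The number was 294 without M2 replicate 2, 330 without M2 replicate 1, 330 without M15 replicate 1 and 1033 without M14 replicate 2. With the scan batch as a block, fitted on arrays, it was 1083, against 1046 on arrays without the block.

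**Figure D2:**
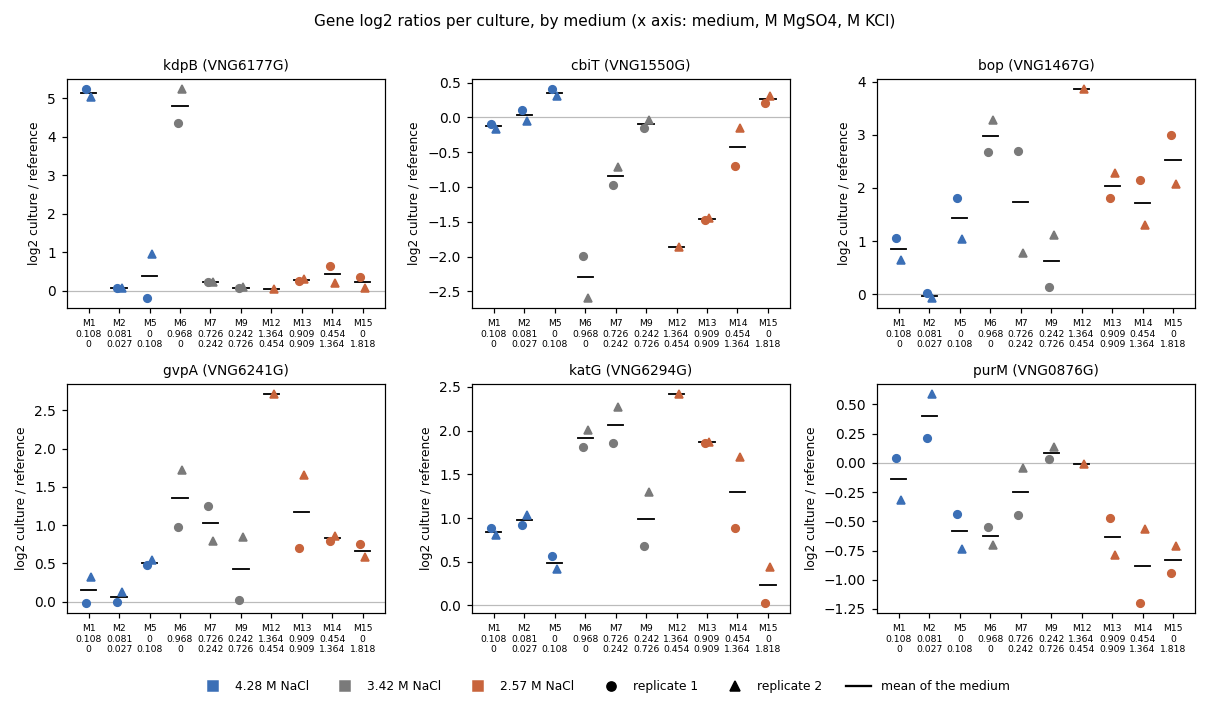
Log2 ratio of culture to reference for kdpB, cbiT, bop, gvpA, katG and purM in each culture, by medium; circles are replicate 1, triangles replicate 2, black lines the mean of a medium and colours the NaCl level. kdpB is high only in M1 and M6 (means of 5.14 and 4.79), and bop is highest in M12 (3.85).

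The comparison of 2.57 M with 4.28 M NaCl asked what low against standard NaCl changes when MgSO4 and KCl make up the balance. Among genes that rose (n = 7 and 6 cultures), bop changed by 1.79 (SE 0.32, adjusted p = 0.00302) and lay above the 4.28 M mean in 7 of 7 cultures. The gas vesicle shell protein gene gvpA (VNG6241G, pNRC200, 191857 to 192084, plus strand) rose by 1.10 (SE 0.19, adjusted p = 0.0024, 7 of 7 cultures), and hop (VNG0180G), for the chloride pump halorhodopsin, by 0.43 (SE 0.10, adjusted p = 0.00954, 7 of 7). katG rose by 0.68 (SE 0.15, adjusted p = 0.00764, 5 of 7) and dmsR (VNG0826C), for the regulator beside the dimethyl sulfoxide reductase genes, by 0.72 (SE 0.17, adjusted p = 0.0116, 6 of 7). Among genes that fell, kdpB changed by -1.62 (SE 0.18, adjusted p = 0.00027, 7 of 7) and kdpA by -1.39 (SE 0.19, adjusted p = 0.000572, 7 of 7), and with media matched in KCl share, which leave out M1, kdpA stood at 0.01. Cobalamin genes cbiT and cbiG (VNG1554G) fell by 0.96 (SE 0.11, adjusted p = 0.00027, 5 of 7) and 0.89 (SE 0.11, adjusted p = 0.000366, 5 of 7). The mean of cbiT was -1.86 in M12 (1 culture), -1.46 in M13, -0.43 in M14 and 0.26 in M15. The fall was thus not shared by all media at 2.57 M, whose MgSO4 went from 1.364 M in M12 to none in M15. Ribosomal protein gene rplX (VNG1702G) fell by 0.52 (SE 0.11, adjusted p = 0.00766), as did the enolase gene eno (VNG1142G), by 0.52. The S-layer glycoprotein gene csg (VNG2679G) at -0.31 (adjusted p = 0.0739) and the arginine deiminase gene arcA (VNG6317G) at -0.23 (adjusted p = 0.235) did not pass the test. Without a symbol, VNG6029G (1.98) and VNG7025 (1.95) rose most, both with repeated probes, and VNG6179G (-1.51) and VNG6178G (-1.42) fell most. These genes were chosen after their values were seen. VNG6029G and VNG7025 have the same coordinates (22513 to 22740, plus strand) on pNRC200 and pNRC100. Here and below they may be 1 signal and do not count as 2 results.

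Lists were called in camera with the preset correlation; none of the 41 calls in the 8 comparisons given here held with an estimated correlation, where the lowest adjusted p was 0.301. fry, which tests whether the genes of a list move one way on balance, called 15. At 2.57 M against 4.28 M, gas vesicle genes were higher (3 of 11 past the test and 8 not, 7 higher adjusted over the list alone, adjusted p = 1.05e-06; adjusted p = 0.496 with an estimated correlation). Retinal protein genes were higher (2 of 6 past the test, 2 adjusted over the list alone, adjusted p = 0.0123; 0.496 with an estimated correlation), and so were phosphate transport genes (2 of 5, 2 adjusted over the list alone, adjusted p = 0.00669; 0.496). Cobalamin genes were lower (4 of 8, 7 adjusted over the list alone, adjusted p = 0.000982; 0.496 with an estimated correlation), as were ribosomal protein genes (4 of 6, 5 adjusted over the list alone, adjusted p = 0.00851; 0.496). Purine synthesis genes were lower (9 of 11, 11 adjusted over the list alone, adjusted p = 0.000982; 0.496 with an estimated correlation). Genes of DNA replication and repair fell in 8 of 23 (8 adjusted over the list alone, adjusted p = 0.0123; 0.689 with an estimated correlation), and tRNA synthetase genes in 5 of 13 (6 adjusted over the list alone, adjusted p = 0.0234; 0.671). Oxidative stress genes were called higher (3 of 7 up, and 4 up and 1 down adjusted over the list alone, adjusted p = 0.0377; 0.496 with an estimated correlation). The plasmid genes were called higher with 28 up and 19 down of 494 (20 and 17 adjusted over the list alone, adjusted p = 5.84e-15; 0.496 with an estimated correlation), and in batch 1 alone their median was -0.18. With the opposite-strand signal as a covariate the plasmid median was -0.07, with 25 up and 23 down, and the list was no longer called. The DNA replication and repair list was not called in camera with the covariate either (1 of 23 down, median -0.12, adjusted p = 0.151). Nor was the tRNA synthetase list (1 of 13 down, median -0.17, adjusted p = 0.111). With M12 left out the retinal, phosphate and oxidative stress lists were no longer called, nor were the tRNA synthetase and DNA replication lists without M5 replicate 1. The oxidative stress call also ended without M1 replicate 2, M5 replicate 2, M6 replicate 1, M6 replicate 2, M13 replicate 1 or M14 replicate 2. Not called were the tetrapyrrole (3 of 6 down, 4 adjusted over the list alone, adjusted p = 0.0509), glycolysis (2 of 12 down, 2 adjusted over the list alone, 0.051), chaperone (0 of 8, and 4 down adjusted over the list alone, 0.181), pyrimidine (1 up and 1 down of 7, the same adjusted over the list alone, 0.189), histidine (1 of 8 down, 3 adjusted over the list alone, 0.203), respiratory (3 of 10 down, 3 adjusted over the list alone, 0.389) and aromatic amino acid lists (0 of 8, 0 adjusted over the list alone, 0.685). Amino acid catabolism (1 of 12 down, 1 adjusted over the list alone) and motility (1 of 14 down, 0 adjusted over the list alone) had an adjusted p of 0.891; the motility test pointed up, against a median of -0.03 and a mean of -0.07.

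In all, 109 genes rose and 375 fell between these levels, 27 of them by 2-fold or more; 838 had an unadjusted p under 0.05. Of the 28 named genes past the test, 17 passed whichever 1 of the 18 cultures of the other media was left out, among them every gene with a symbol given above as rising or falling, but without M12 katG stood at 0.36 and no longer passed. Only 9 of the 28 passed under all scalings (Agilent's log ratios, the authors' values and median centring) and 6 under every alternative. With media matched in KCl share 10 of the 28 kept their call, 17 no longer passed and 1, kdpA, changed sign. That fit uses fewer media, so a lost call may also come from lower precision. The calls of hop, katG, dmsR, rplX and eno each ended under at least 1 scaling. The count of 484 was 243 without M2 replicate 2, 258 without M2 replicate 1, 232 without M1 replicate 1, 277 without M5 replicate 1, 282 without M13 replicate 2, 277 without M15 replicate 1 and 854 without M14 replicate 2. With the scan batch as a block, fitted on arrays, it was 617, against 614 on arrays without the block, which moved values by a median of 0.002, and in batch 1 alone it was 215. With culture density as a covariate it was 310, of which 301 were among the 484. Without M12, 385 of the 484 genes still passed. Of the 484 genes, which were called from both batches together, 484 had the same sign in batch 1 and 480 in batch 2. Over all genes the values of the batches correlated at 0.035 (across genes, which are not independent replicates). Here and below, the choice of genes from both batches favours a shared sign, so such counts are no replication. With the opposite-strand signal as a covariate 365 genes passed, of which 203 fell and 290 were among the 484, and 169 passed without the 9 cultures of high opposite-strand signal. With the covariate bop changed by 2.09, gvpA by 1.18 and cbiT by -0.94. A model of 2 groups that ignored the medium within a NaCl level called 0 genes in limma, with 699 at an unadjusted p under 0.05. The median of all genes was -0.09 here, -0.14 with Agilent's log ratios, -0.10 with the authors' values and -0.18 after median centring, and the share of calls that rose was 22.5%, against 45.5% with the authors' values.

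The comparison of 3.42 M with 4.28 M asked the same of intermediate NaCl (n = 6 and 6 cultures). katG rose by 0.89 (SE 0.15, adjusted p = 0.005, 5 of 6 cultures above the 4.28 M mean), and queC (VNG6303G, pNRC200, 235663 to 236310, minus strand), of the synthesis of the tRNA base archaeosine, rose by 0.46 (SE 0.09, adjusted p = 0.0115), a call that ended under 2 scalings and 8 other alternatives. Cobalamin genes fell: cbiT changed by -1.16 (SE 0.12, adjusted p = 4.44e-05, 6 of 6 cultures) and cbiG by -1.09 (SE 0.12, 6 of 6). The means of cbiT were -2.29 in M6, -0.84 in M7 and -0.095 in M9. They were -0.13 in M1, 0.03 in M2 and 0.35 in M5. The fall thus lay mostly in M6 and M7, which held more MgSO4 (0.968 M and 0.726 M) than M9 (0.242 M). NaCl and MgSO4 cannot be told apart here. cobN (VNG1566G) changed by -0.76 and cbiQ (VNG1632G) by -0.61. For bop (1.03, adjusted p = 0.176), gvpA (0.69, adjusted p = 0.11) and kdpA (-0.18, adjusted p = 0.79) no difference passed the test. VNG6029G (1.08) and VNG2193Gm (1.01) rose most among genes without a symbol, and VNG2383G (-1.65) and VNG1240G (-1.39) fell most, all chosen after their values were seen; the call of VNG6029G ended without any 1 of 13 cultures. Of 10 named genes past the test, 2 passed under all scalings and 1 under every alternative; the calls of katG, cbiG, cobN and cbiQ each ended under at least 1 scaling. Cobalamin genes were called lower (4 of 8, 4 adjusted over the list alone, adjusted p = 1.35e-07; 0.525 with an estimated correlation). The respiratory list was called higher with 0 of 10 members past the test (2 adjusted over the list alone, adjusted p = 0.0176; 0.954), and the purine list lower with 0 of 11 (0 adjusted over the list alone, adjusted p = 0.0176; 0.954). The respiratory call ended without M1 replicate 2, M2 replicate 2 or M6 replicate 1, and the purine call without M1 replicate 1, M2 replicate 2, M5 replicate 1 or M7 replicate 1. In all, 16 genes rose and 37 fell, 16 of them by 2-fold or more, and 295 had an unadjusted p under 0.05. The count of 53 was 35 without M2 replicate 2 and 35 without M9 replicate 2; it was 107 with the scan batch as a block and 89 in batch 1 alone, and all 53, which were called from both batches together, had the same sign in each batch, where over all genes the batches correlated at 0.389. With culture density as a covariate 25 genes passed, 16 of them among the 53, and cobN (-0.56), cbiQ (-0.28), queC (0.42) and VNG6029G (1.04) did not. The respiratory and purine lists were not called with it. Density was 0.408 to 0.439 at 3.42 M and 0.432 to 0.523 at 4.28 M, so it is largely confounded with NaCl here. A model of 2 groups that ignored the medium called 0 genes in limma, with 164 at an unadjusted p under 0.05. The share that rose was 30.2%, and 47.4% with the authors' values.

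Replacing MgSO4 by KCl at 2.57 M NaCl was examined as a slope, printed as the change from no KCl to no MgSO4 in the remainder (M12 to M15, 7 cultures, with the lowest share at 0.25). cbiT rose by 2.95 (SE 0.31, adjusted p = 9.65e-05), cbiG by 2.47 (SE 0.30) and cbiQ by 2.40 (SE 0.27). The chemotaxis gene cheF1 (VNG0964C), which links the chemotaxis system to the motor, rose by 1.73 (SE 0.28, adjusted p = 0.00264). katG fell by 2.85 (SE 0.39, adjusted p = 0.000851) and queC by 1.37. pstC (VNG2484G), for a permease of the phosphate transporter, fell by 1.66 (SE 0.22, adjusted p = 0.000655), and gvpA fell by 2.59 (SE 0.50, adjusted p = 0.00851). Without M12, with its 1 culture, pstC (-0.55) and gvpA (-1.03) no longer passed, and in batch 2, which lacks M12, gvpA stood at 0.11. VNG2383G (3.82) and VNG0535C (3.54) rose most among genes without a symbol and VNG7025 (-3.60) and VNG6029G (-3.49) fell most, chosen after their values were seen. Without M12 VNG7025 (-1.93) no longer passed. The means of VNG2383G in M12, M13, M14 and M15 were -2.86, -2.75, -2.28 and 0.17. Those of VNG0535C were -2.95, -2.89, -2.90 and 0.00. Both thus changed mostly in M15, the medium without MgSO4, and not evenly along the line. Under at least 1 scaling the calls of cbiG, cbiQ and cheF1 ended, and 7 of 19 named genes passed under all scalings and 1 under every alternative. Called lists were phosphate transport, lower (2 of 5, 5 adjusted over the list alone, adjusted p = 0.000157; 0.847 with an estimated correlation), and cobalamin, higher (4 of 8, 4 adjusted over the list alone, adjusted p = 0.0288; 0.954). Purine genes were called lower with 0 of 11 past the test (0 adjusted over the list alone, adjusted p = 0.0288; 0.954 with an estimated correlation). Amino acid catabolism was called lower with 1 up and 1 down of 12 (2 and 1 adjusted over the list alone, adjusted p = 0.0288; 0.954), and plasmid genes higher with 6 up and 11 down of 494 (5 and 11 adjusted over the list alone, adjusted p = 0.00114; 0.954). Without M12 the median of the plasmid genes was -0.09, and with the opposite-strand covariate it was 0.15. Without M12 the purine, amino acid catabolism and plasmid lists were not called; the plasmid call also ended without M14 replicate 1, and the purine call without M13 replicate 1, M14 replicate 2 or M15 replicate 2. Motility genes were not called (3 of 14 up, adjusted p = 0.0672). In all, 101 genes rose and 54 fell, 129 of them by 2-fold or more, and 589 had an unadjusted p under 0.05. The count of 155 was 241 without M14 replicate 2, 236 without M14 replicate 1, 89 without M15 replicate 2 and 66 without M15 replicate 1. It was 315 with the scan batch as a block and 274 with the opposite-strand covariate. Of the 155, which were called from both batches together, 153 kept their sign in batch 2. Without M12, 83 of the 155 still passed. With the covariate the plasmid list was not called. The share that rose was 65.2%, against 47.0% with Agilent's log ratios and 36.4% with the authors' values, whose medians of all genes were -0.13 and -0.24.

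The same slope at 3.42 M NaCl (M6, M7 and M9, 6 cultures) contained the medium M6 without added KCl. It is printed as the change from no KCl to no MgSO4, although the highest share was 0.75, so the values extend the line beyond the media measured. The means of kdpB were 4.79 in M6, 0.23 in M7 and 0.09 in M9. Along the line kdpB fell by 5.42 (SE 0.42, adjusted p = 1.38e-05) and kdpA fell by 5.21 (SE 0.44). cbiT rose by 2.72 (SE 0.26, adjusted p = 2.45e-05), cbiQ by 2.66, cbiG by 2.43 and cobN by 1.94 (SE 0.25). bop fell by 3.01 (adjusted p = 0.0312), a call that ended without any single one of M6 replicate 1, M6 replicate 2, M9 replicate 1 or M9 replicate 2. The iron storage gene dpsA (VNG2443G) fell by 1.03, a call that ended without M9 replicate 1 and under all 3 scalings. Of 15 named genes, 7 passed under all scalings and 6 under every alternative. VNG1634G (2.73) and VNG1564H (2.63) rose most among genes without a symbol and VNG6179G (-4.84) and VNG6178G (-4.81) fell most, chosen after their values were seen. Purine synthesis genes were called higher (5 of 11, 9 adjusted over the list alone, adjusted p = 3.71e-09; 0.301 with an estimated correlation), as were cobalamin genes (4 of 8, 4 adjusted over the list alone, adjusted p = 9.95e-09; 0.301) and ribosomal protein genes (3 of 6, 6 adjusted over the list alone, adjusted p = 1.66e-05; 0.301). Oxidative stress genes were called lower (2 of 7, 2 adjusted over the list alone, adjusted p = 0.0476; 0.698 with an estimated correlation), a call that ended without either culture of M1 or of M5, M6 replicate 1 or M9 replicate 1. In all, 78 genes rose and 42 fell, 86 of them by 2-fold or more, and 398 had an unadjusted p under 0.05. The count of 120 was 65 without M9 replicate 2, 73 without M6 replicate 1 and 36 without M9 replicate 1. It was 225 with the scan batch as a block and 36 in batch 1 alone. Of the 120, which were called from both batches together, 110 kept their sign in batch 2, and over all genes the batches correlated at 0.315. With the opposite-strand covariate the oxidative stress list was not called in camera (2 of 7 down, median -0.38, adjusted p = 0.0579). The share that rose was 65.0%, and 54.5% after median centring.

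At 4.28 M NaCl, where KCl and MgSO4 are both scarce (M1, M2 and M5, 6 cultures), kdpB fell by 3.55 (SE 0.31, adjusted p = 1.05e-05) and kdpA by 3.17 (SE 0.32) with the KCl share. The cell division gene ftsZ (VNG0192G) rose by 1.05 (SE 0.14, adjusted p = 0.000204). The glutamate dehydrogenase gene gdhB (VNG0161G) rose by 0.96 (SE 0.14) and the superoxide dismutase gene sod (VNG1332G) by 0.90 (SE 0.18, adjusted p = 0.00449). thiC (VNG0715G), of thiamine synthesis, fell by 1.52 (SE 0.24, adjusted p = 0.000992) and queC by 1.13 (SE 0.14, adjusted p = 0.000171). arcD (VNG6313G), for the exchanger of arginine and ornithine, fell by 1.72, a call that ended without M5 replicate 1. The calls of ftsZ, gdhB and sod ended under 2 scalings each, and of 23 named genes 6 passed under all scalings and 4 under every alternative. VNG6262G (3.89) and VNG6264G (3.66) rose most among genes without a symbol and VNG1490H (-4.05) and VNG6179G (-3.37) fell most, chosen after their values were seen. The means of VNG6262G were -0.57 in M1, -0.72 in M2 and 3.00 in M5, so it changed mostly in the medium without MgSO4. In the same order the means of ftsZ were -0.01, 0.15 and 1.02, and those of gdhB 0.20, 0.15 and 1.07. Those of thiC were -0.51, -0.53 and -1.92, and those of queC 0.83, 1.32 and -0.08. These genes too changed mostly in M5 and not evenly along the line. The cultures of M5 also enter the comparison of MgSO4-free media, so a gene called in both does not count as 2 results. Ribosomal protein genes were called lower (3 of 6, 5 adjusted over the list alone, adjusted p = 0.016; 0.911 with an estimated correlation), as were respiratory genes (3 of 10, 4 adjusted over the list alone, adjusted p = 0.0314; 0.911). Oxidative stress genes were called higher (4 of 7, 4 adjusted over the list alone, adjusted p = 0.0288; 0.911 with an estimated correlation). Gas vesicle genes were called higher with 0 of 11 past the test and tRNA synthetase genes lower with 0 of 13, both with 0 adjusted over the list alone and with an adjusted p of 0.0288 (0.911 with an estimated correlation). Each of these 5 calls ended when 1 culture was left out: M5 replicate 1 for all but the tRNA synthetases, M5 replicate 2 for the respiratory, oxidative stress and tRNA synthetase lists, M1 replicate 1 for the gas vesicle, respiratory and tRNA synthetase lists, and M1 replicate 2 for oxidative stress. In all, 204 genes rose and 145 fell, 86 of them by 2-fold or more, and 647 had an unadjusted p under 0.05. The count of 349 was 189 without M1 replicate 1 and 141 without M5 replicate 1, and it was 74 in batch 1 alone. All 349, which were called from both batches together, had the same sign in both. The share that rose was 58.5%, and 71.0% after median centring; the median of all genes was -0.11 with the authors' values.

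Whether the KCl share acts differently at low and standard NaCl was tested as the slope at 2.57 M minus that at 4.28 M. The share is a proportion: its full unit is 1.818 M of salt at 2.57 M and 0.108 M at 4.28 M. Slopes can therefore differ without an effect of NaCl itself. kdpB (3.82, SE 0.58, adjusted p = 0.00291) and kdpA (3.82, SE 0.60) had a higher slope at 2.57 M, where no medium lacked KCl. cbiT (2.49, SE 0.36, adjusted p = 0.00291), cbiQ (2.13) and cbiG (2.05) also had a higher slope there. The slope of pstC was lower (-1.54, SE 0.26, adjusted p = 0.00558), as was that of katG (-2.42, adjusted p = 0.0118), and the slope of gvpA fell by 3.00 (adjusted p = 0.0137) from 4.28 M to 2.57 M. The call of gvpA ended without M15 replicate 2, as did that of VNG7025 given below, and that of katG without M15 replicate 1. Those of cbiT, cbiQ, cbiG and katG ended under 2 scalings each. Of 13 named genes, 5 passed under all scalings and none under every alternative. Without M12 gvpA (-1.44), pstC (-0.42) and VNG7025 (-2.45) no longer passed. VNG6178G (3.55) and VNG6179G (3.48) were highest among genes without a symbol and VNG7025 (-4.11) and VNG6029G (-4.02) lowest, chosen after their values were seen. Phosphate transport was called lower (2 of 5, 2 adjusted over the list alone, adjusted p = 0.000529; 0.978 with an estimated correlation) and cobalamin higher (4 of 8, 4 adjusted over the list alone, adjusted p = 0.000749; 0.978). Amino acid catabolism was called lower (1 of 12, 2 adjusted over the list alone, adjusted p = 0.017; 0.978 with an estimated correlation) and plasmid genes higher (7 up and 10 down of 494, 8 and 10 adjusted over the list alone, adjusted p = 0.000529; 0.978). Without M12 the median of the plasmid genes was -0.17, without M5 replicate 1 it was 0.19, and with the opposite-strand covariate it was 0.18. The plasmid and amino acid catabolism calls ended without M12, M1 replicate 2 or M5 replicate 1, and the plasmid call also without M14 replicate 1. In all, 29 genes had a higher and 38 a lower slope, 66 of them by 2-fold or more, and 312 had an unadjusted p under 0.05. The count of 67 was 41 without M15 replicate 1, 128 with the scan batch as a block and 27 in batch 1 alone. Of the 67, which were called from both batches together, 62 kept their sign in batch 2. Without M12, 34 of the 67 still passed. With the covariate neither the plasmid nor the amino acid catabolism list was called. The share that was higher was 43.3%, and 27.8% with the authors' values, whose median of all genes was -0.12.

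Media without added MgSO4 (M5 and M15, 4 cultures) were set against the nearest media with it at the same NaCl (M2 and M14, 4 cultures). The threonine synthase gene thrC (VNG2430G) rose by 1.07 (SE 0.13, adjusted p = 0.000102), argH (VNG2436G), of arginine synthesis, by 1.04 (SE 0.24, adjusted p = 0.00848) and sod (VNG1332G) by 0.86 (SE 0.13). The second superoxide dismutase gene, sod (VNG1190G), rose by 0.62 (SE 0.10), and hop rose by 0.69 (SE 0.12, adjusted p = 0.0017). thiC fell by 1.42 (SE 0.18, adjusted p = 9.82e-05), queC by 1.18 (SE 0.11, adjusted p = 8.16e-06) and arcD (VNG6313G) by 1.37 (SE 0.26, adjusted p = 0.00303). The respiratory complex genes nuoK (VNG0643G) and nuoL (VNG0646G) fell by 0.49 each. These genes changed in their direction in 4 of 4 cultures. Under at least 1 scaling the calls of both sod genes, hop, nuoK and nuoL ended, and of 22 named genes 6 passed under all scalings and 4 under every alternative. katG fell by 0.78, a call that ended without M15 replicate 1, and bop at 1.13 (adjusted p = 0.064) did not pass. VNG6262G (3.12) and VNG0535C (3.00) rose most among genes without a symbol and VNG1490H (-2.83) and VNG1187G (-1.47) fell most, chosen after their values were seen. Called lower were respiratory genes (3 of 10, 5 adjusted over the list alone, adjusted p = 0.0206; 0.949 with an estimated correlation), ribosomal protein genes (2 of 6, 4 adjusted over the list alone, adjusted p = 0.00915; 0.949), phosphate transport (1 of 5, 4 adjusted over the list alone, adjusted p = 0.0296; 0.949) and purine synthesis (0 of 11, 0 adjusted over the list alone, adjusted p = 0.0414; 0.949). The phosphate call ended without M5 replicate 2 or M14 replicate 1, and the purine call without M2 replicate 2, M5 replicate 2, M15 replicate 2 or either culture of M14. With the opposite-strand covariate the phosphate list was not called in camera (0 of 5, median -0.39, adjusted p = 0.0646). Nor was the purine list (1 of 11 down, median -0.19, adjusted p = 0.0698). Oxidative stress genes were not called (4 up and 1 down of 7, 5 up and 1 down adjusted over the list alone, adjusted p = 0.0555). In all, 324 genes rose and 120 fell, 64 of them by 2-fold or more, and 767 had an unadjusted p under 0.05. The count of 444 was 237 without M2 replicate 2 and 267 without M15 replicate 1, and 575 genes passed with the opposite-strand covariate. All 444, which were called from both batches together, had the same sign in both. The share that rose was 73.0%, and 83.3% after median centring. The interaction with NaCl passed for 1 gene, VNG0319H (-1.46, SE 0.17, adjusted p = 0.00321), with 321 at an unadjusted p under 0.05; its mean went from -0.32 in M2 to 2.19 in M5 and from -0.14 in M14 to 0.91 in M15. That count was 2 without either culture of M1, 11 without either culture of M7, 19 without M15 replicate 2 and 169 without M14 replicate 2.

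Media without added KCl (M1 and M6, 4 cultures) were set against M2 and M7 (4 cultures). kdpB rose by 4.82 (SE 0.23, adjusted p = 3.91e-08) and kdpA by 4.64 (SE 0.24), each in 4 of 4 cultures, and cbiT fell by 0.81 (SE 0.14, adjusted p = 0.00735, 4 of 4). The mean of cbiT was -0.13 in M1 against 0.03 in M2, but -2.29 in M6 against -0.84 in M7. That of cbiG was 0.14 against 0.29 and -1.85 against -0.53. Most of both falls thus came from 3.42 M NaCl, where MgSO4 also differed (0.968 M in M6, 0.726 M in M7). argH rose by 1.24 (adjusted p = 0.0102) and cbiG fell by 0.74, calls that ended without M7 replicate 2 or without M2 replicate 1. The comparison of MgSO4-free media, where argH also rose, subtracts M2 as well. Calls of like direction in both may therefore come in part from M2. The mean of argH was lowest in M2 (0.69), against 2.20 in M1 and 1.98 in M5. It was also higher in M6 (1.82) than in M7 (0.85), and in M15 (1.89) than in M14 (1.09). The calls of cbiT, cbiG and argH ended under at least 1 scaling, and of 13 named genes 2 passed under all scalings and 2 under every alternative. VNG6179G (4.54) and VNG6178G (4.35), which lie beside kdpB, rose most among genes without a symbol, and VNG1564H (-0.84) and VNG1553G (-0.78) fell most; they were chosen after their values were seen. Cobalamin genes were called lower (4 of 8, 4 adjusted over the list alone, adjusted p = 6.46e-05; 0.554 with an estimated correlation), as were purine genes (3 of 11, 10 adjusted over the list alone, adjusted p = 2e-06; 0.554) and phosphate transport genes (2 of 5, 2 adjusted over the list alone, adjusted p = 0.000671; 0.554). Pyrimidine genes were called lower (1 of 7, 3 adjusted over the list alone, adjusted p = 0.0181; 0.651 with an estimated correlation), ribosomal protein genes lower with 0 of 6 past the test (0 adjusted over the list alone, adjusted p = 0.00945; 0.662), and plasmid genes higher with 15 up and 4 down of 494 (15 and 5 adjusted over the list alone, adjusted p = 0.00945; 0.974). Without M1 replicate 2 the median of the plasmid genes was -0.08, and their call also ended without M2 replicate 1, M6 replicate 2 or M7 replicate 1. The pyrimidine call ended without M1 replicate 1 or M7 replicate 2, and the ribosomal call without M7 replicate 2. The purine, phosphate and ribosomal lists were called lower in MgSO4-free media too, and the shared cultures of M2 may have a part in that. In all, 33 genes rose and 48 fell, 15 of them by 2-fold or more, and 353 had an unadjusted p under 0.05. The count of 81 was 47 without M1 replicate 2, 41 without M2 replicate 1, 41 without M2 replicate 2 and 46 without M7 replicate 2. It was 154 with the scan batch as a block. Of the 81, which were called from both batches together, 80 kept their sign in batch 2. The share that rose was 40.7%, 51.2% with Agilent's log ratios, 94.4% with the authors' values and 100% after median centring. The interaction with NaCl passed for 0 genes in limma, with 43 at an unadjusted p under 0.05; it passed for 3 without M6 replicate 2 and 1 without M7 replicate 2.

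Each medium was also compared with the standard medium M2, whose 2 cultures all 9 comparisons share. In M1, kdpB (5.07) and kdpA (4.90) rose, and in M6 they rose by 4.73 and 4.61 while cbiT (-2.32), cbiG (-2.14) and cobN (-1.73) fell. In M13 cbiT fell by 1.49, and in M15 thrC (1.29), sod (VNG1332G, 1.25) and hop (1.10) rose and queC (-1.55) and thiC (-1.29) fell. In M5, sod (VNG1332G) rose by 1.06 and queC and thiC each fell by 1.40. These calls held whichever 1 of the 18 cultures of the media other than M12 was left out. Those of sod in M5 and M15 and of hop in M15 ended under at least 1 scaling. In the 1 culture of M12, bop lay above M2 by 3.88, gvpA by 2.64 and cbiT below it (-1.89); all 3 passed, but with a spread taken from other media, and nothing tests whether another culture of M12 would give them. In M14 the purine synthesis genes purQ (VNG1945G, -1.36), purM (VNG0876G, -1.28) and purD (VNG1305G, -1.27) fell, calls that ended without M14 replicate 1, M2 replicate 1 or M2 replicate 2. They also ended with the opposite-strand covariate, as SE rose: purQ went from -1.36 (SE 0.26) to -1.30 (SE 0.34), purM from -1.28 (SE 0.23) to -1.14 (SE 0.30) and purD from -1.27 (SE 0.23) to -1.15 (SE 0.29).

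The numbers of genes higher and lower than in M2 were 17 and 0 in M1, 169 and 144 in M5, 125 and 134 in M6, 16 and 6 in M7, 0 and 0 in M9 (limma, 43 at an unadjusted p under 0.05), 84 and 132 in M12 (1 culture), 68 and 110 in M13, 63 and 355 in M14, and 215 and 272 in M15. The sum was 1910, of 854 different genes. Without M2 replicate 2 or M2 replicate 1 the sum was 345 or 608, and without M14 replicate 2 or M15 replicate 1 it was 3279 or 1261. Without M2 replicate 2 the counts were 78 in M5, 56 in M6, 2 in M7, 39 in M12, 28 in M13, 0 in M14 (limma, 664 at an unadjusted p under 0.05) and 130 in M15. Without M2 replicate 1 they were 136, 119, 2, 78, 21, 4 and 236 in the same order. M5 had 184 without its replicate 2 and 204 without its replicate 1, M7 had 66 and 5, and M15 had 237 and 138. M13 had 21 without its replicate 2 and 333 without either culture of M14. M14 had 1207 without its replicate 2 and 0 without its replicate 1 (limma, 358 at an unadjusted p under 0.05). The cultures of M14 had an opposite-strand signal of 3.00 and 2.33, against 1.58 and 1.64 in M2, and its count of 418 was 60 with that signal as a covariate and 14 in batch 1 alone. The share of the sum that was higher was 39.6%, and 53.0% with the authors' values.

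Because of the shared controls, part of the overlap between these comparisons may come from M2. M5 and M15, the media without MgSO4, shared 151 higher and 139 lower genes, where independent calls would share 14.9 and 16.1 and simulations without any change gave 0 and 0. Their covariance across genes was 0.274, against 0.0405 simulated. M13 and M14 shared 42 higher and 92 lower genes (independent 1.8 and 16, simulated 6.87 and 10.4, covariance 0.266 against 0.0347). M1 and M6, the media without KCl, shared 16 higher genes (independent 0.9, simulated 0, covariance 0.132 against 0.0309). The simulations held no change in any medium, so few genes passed in most of them. The simulated counts therefore cannot show how much overlap the shared cultures of M2 add among real calls. The covariances do not depend on calls. In fits chosen after seeing the data, M2 was split so that each medium of a pair was set against its own culture of M2, both ways. M5 and M15 then shared 54 higher and 21 lower genes one way and 69 and 28 the other, with covariances of 0.272 and 0.263. M1 and M6 shared 12 higher genes either way (covariance 0.115 and 0.137). M13 and M14 shared 2 higher and 2 lower genes one way and 0 the other, where M14 had 0 calls in limma (664 at an unadjusted p under 0.05), and their covariance was 0.265 and 0.254.

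**Figure D3:**
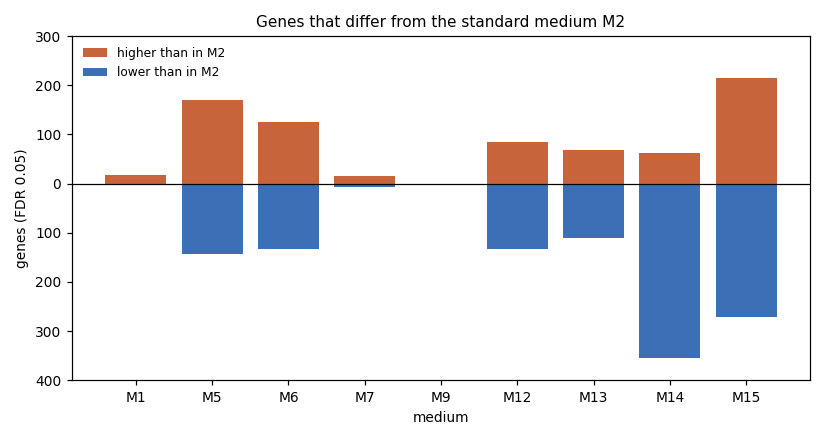
Number of genes higher and lower than in M2 past the test, by medium; bars start at 0. M14 (355) and M15 (272) have the most genes lower and M9 has none in either direction.

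Lists with fewer than 5 named members were read by gene. For potassium transport these were kdpA and kdpB, and for cell surface csg, for iron dpsA, and for dimethyl sulfoxide respiration dmsR, all given above. In the arginine fermentation list arcD (VNG6313G) fell in MgSO4-free media as given, arcD (VNG2123G) fell there by 0.39 (adjusted p = 0.00392), and arcA and the carbamate kinase gene arcC (VNG6316G) passed in none of the comparisons. In the sulfur list cysS (VNG1097G) passed in none and cysE (VNG1481G) fell against M2 in M14 (-0.68) and M15 (-0.56).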

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

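The tests of the NaCl of the medium, of genes in batch 1 alone as a sign of batch, of background relative to the gene-strand signal, and of genes lower at 2.57 M NaCl were chosen after the result was seen, as were the fits with the opposite-strand signal as a covariate and the unadjusted counts of the splits.

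The effect of the KCl share differed between 2.57 M and 4.28 M NaCl for 67 genes, by a test of the difference of slopes in limma; the count was 41 without M15 replicate 1. The slopes do not span the same media, since no medium at 2.57 M lacked KCl. A full unit of the share also stands for 1.818 M of salt at 2.57 M and 0.108 M at 4.28 M. A difference of slopes therefore does not by itself show an effect of NaCl. The effect of leaving out MgSO4 differed between NaCl levels for 1 gene, VNG0319H, by a test of the interaction, with 321 genes at an unadjusted p under 0.05. Without M14 replicate 2 that count was 169, without M15 replicate 2 it was 19, without either culture of M7 11, and without either culture of M1 2. Another result lies outside the gene values: probes on the strand opposite to genes had a median above the control spots in every culture, by 1.35 (log2) in the lowest culture (M7 replicate 1) and by 3.00 in the highest (M14 replicate 1). The reference channel gave 1.33 to 1.94 on the same scale.

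The opposite-strand signal was weighed first. Control spots and opposite-strand probes, each relative to the gene-strand signal, did not rise together over the 19 cultures (Spearman rho -0.158), which argues against unspecific background, while the plain ratio of their rises (0.54) moves with the brightness of an array and decides nothing. NaCl of the medium as the whole source is argued against by the gap between replicates of a medium, which was 1.092 times the gap between the means at 2.57 M and 4.28 M. DNA carried over with the RNA remains open: the dim end of the opposite-strand probes rose with their median at a slope of 0.922, which is consistent with signal added at all loci, although the labels state DNase treatment. The spread of these probes did not fall as their median rose (rho 0.277). The same rho was 0.544 on the 40 reference channels, so this measure follows brightness and does not decide. Opposite-strand probes were also set against those opposite to the deleted ura3. They lay 0.74 (M14 replicate 2) to 2.13 (M14 replicate 1) above these in the 9 cultures with a signal over 1.8. In the other cultures they lay 0.28 (M9 replicate 1) to 0.69 (M2 replicate 2) above. A deleted locus gives neither DNA nor antisense RNA, so these values do not tell the 2 apart. Antisense RNA at all loci was not tested.

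Genes that differ between 2.57 M and 4.28 M NaCl were weighed next. With the opposite-strand signal as a covariate 365 genes passed, 290 of them among the 484 called without it, which argues against this signal as the whole cause; for the lower genes the covariate gave 203 where 375 were called without it, and there the signal and NaCl cannot be told apart, because the signal was higher at 2.57 M. On arrays the scan batch as a block gave 617 genes and no block 614, but the block moved values by a median of only 0.002 and decides nothing. Inside batch 1 alone 215 genes passed, which argues against a shift between the batches as the whole cause. That fit had only 2 residual degrees of freedom, from the cultures of M2 and M6 alone, so its count is uncertain. An effect that differs by batch stays open, since the batches correlated at 0.035 across genes. In 2 groups of cultures, with no account of the medium, limma called 0 genes in the real split (699 at an unadjusted p under 0.05), so 100 of 100 splits gave as many (highest 624) and the count says nothing about chance, as at 3.42 M against 4.28 M (0 in limma, 164 unadjusted, 100 of 100, highest 245); 5 and 41 of 100 splits gave as many unadjusted. With a mean for each medium, 3 of 35 splits gave at least the 484 genes (7 of 35 with the covariate) and M5, M13, M14 and M15 against M1, M2 and M12 gave 634, groups that differ in both KCl share (0.65) and opposite-strand signal (0.53), so the cause stays open, and at 3.42 M 7 of 10 splits gave at least the real 53, with a median of 89 and a highest of 420 in the others.

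Media without MgSO4 or without KCl were weighed last. With the opposite-strand signal as a covariate 575 genes passed for MgSO4-free media, against 444, which argues against this signal as the whole cause. In a model of 2 groups, the real split of 4 and 4 cultures gave 347 genes, 2 of 35 splits gave as many, and the highest other gave 800, so chance was not excluded at a share of 0.05. That other split set both cultures of M2, M14 replicate 2 and M5 replicate 1 against the rest, groups whose opposite-strand signal differed by 0.56, against 0.25 in the real split, and it points to a structure of the cultures beside MgSO4. For KCl-free media the real split gave 38 genes, 2 of 35 gave as many, and the highest other, 144, was the split by NaCl level.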

How the results depend on the processing

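Fits with the opposite-strand signal as a covariate or subtracted, without the 9 cultures of high opposite-strand signal, of arrays as single values and of M2 split between media were chosen after seeing the data. Counts are genes past the test unless said otherwise, and only counts that moved by more than 1.5 times are given; the cause was not tested except where stated. Between-array quantile normalisation left the log ratios unchanged by construction. The mean of probes, no filter, technical replicate 2 left out, M12 left out, a trended robust prior and the replicate block moved no count of a comparison in this way, although replicate numbers do not pair the cultures. Without M12, however, 385 of the 484 calls for 2.57 M against 4.28 M were shared, 83 of the 155 for the slope at 2.57 M and 34 of the 67 for the difference of slopes. Of 186 results for named genes past the test, 186 were kept with at least 1 probe, 183 without background correction, 120 with Agilent's log ratios and 91 after median centring. With the authors' values 72 were kept and 114 were not.

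With Agilent's log ratios the counts were 248 for the F test, 200 for 2.57 M against 4.28 M, 66, 63 and 127 for the KCl slopes at 2.57 M, 3.42 M and 4.28 M, 44 for their difference, 194 for MgSO4-free and 43 for KCl-free media, 0 for the MgSO4 interaction (limma, 211 at an unadjusted p under 0.05) and 714 for the sum against M2. With the authors' values they were 155, 88, 44, 38, 78, 18, 111, 18, 0 (limma, 211 unadjusted) and 370 in the same order, with 23 lists called. After median centring they were 157 for the F test, 28 for 3.42 M against 4.28 M, 37, 33 and 93 for the slopes, 18 for their difference, 132 and 18 for MgSO4-free and KCl-free media, and 607 against M2. At least 1 probe per gene gave 201 for the slope at 3.42 M. For the MgSO4 interaction, no background correction gave 2 and the stricter filter 9.

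The correlation within cultures could not be estimated on the 20 hybridised samples, which repeat 1 culture, so the block fits used 40 arrays tied by culture (estimated correlation 0.622 with the scan batch, 0.428 with the slide, 0.632 with neither). With the scan batch as a block the counts were 1083 for the F test, 107 for 3.42 M against 4.28 M, 315 and 225 for the slopes at 2.57 M and 3.42 M, 128 for the difference of slopes, 154 for KCl-free media, 65 and 12 for the MgSO4 and KCl interactions, and 3342 against M2. Arrays without a block gave 1046, 102, 306, 226, 119, 156, 64, 12 and 3177 in the same order, so most of the rise came with arrays as values. With the slide as a block they were 1674 for the F test, 169 for 3.42 M against 4.28 M, 559 and 701 for the slopes at 2.57 M and 4.28 M, 335 for their difference, 832 and 237 for MgSO4-free and KCl-free media, 367 and 21 for the interactions, and 4502 against M2. For 2.57 M against 4.28 M the batch block gave 617 and arrays without a block 614. Batch 1 alone gave 215 for 2.57 M against 4.28 M, 89 for 3.42 M against 4.28 M, 36 and 74 for the slopes at 3.42 M and 4.28 M, 27 for the difference of slopes, and 0 (limma, 421 unadjusted) and 190 for the interactions.

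Only the media compared gave 285, 42 and 193 for the slopes at 2.57 M, 3.42 M and 4.28 M, 287 for MgSO4-free media, 13 for their interaction and 4761 against M2. Culture density as a covariate gave 850 for the F test, 310 and 25 for the NaCl comparisons (301 of the 484 and 16 of the 53 calls shared), 2 for the KCl interaction and 997 against M2. At a rate of 0.01, which is stricter by construction, the counts were 232 for the F test, 179 and 29 for the NaCl comparisons, 60, 43 and 157 for the slopes, 33 for the difference of slopes, 219 and 37 for MgSO4-free and KCl-free media, and 566 against M2. Media matched in KCl share, which use fewer media, gave 99 for 2.57 M against 4.28 M. The opposite-strand covariate gave 274 for the slope at 2.57 M and 130 for KCl-free media, and the subtracted signal gave 268 for that slope and 2 for the MgSO4 interaction. The covariate kept 290 of the 484 calls for 2.57 M against 4.28 M, and it ended the calls of the DNA replication, tRNA synthetase and plasmid lists there. The covariate also ended the phosphate and purine calls for MgSO4-free media (adjusted p = 0.0646 and 0.0698 in camera). So did the oxidative stress call for the slope at 3.42 M end (adjusted p = 0.0579). The plasmid calls for the slope at 2.57 M and the difference of slopes ended too, as did the amino acid catabolism call for that difference. Motility at 2.57 M and for the difference of slopes, and plasmid genes for the slope at 3.42 M, were called with the covariate and not without it. Without the 9 cultures the counts were 169 for 2.57 M against 4.28 M, 194 for the slope at 3.42 M and 19 for KCl-free media. Of 41 list calls, 0 held with the estimated correlation (camera, 5 of 152 at an unadjusted p under 0.05), and fry made 15. Of the 41, 18 held whichever 1 culture was left out, M12 included.

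Leaving out each culture in turn gave 294 to 1033 for the F test, 232 to 854 for 2.57 M and 35 to 68 for 3.42 M against 4.28 M, 66 to 241, 36 to 174 and 141 to 451 for the slopes at 2.57 M, 3.42 M and 4.28 M, 41 to 82 for the difference of slopes, 237 to 568 and 41 to 112 for MgSO4-free and KCl-free media, 1 to 169 and 0 to 3 (limma, 43 unadjusted with all cultures) for their interactions, 345 to 3279 against M2 and 35 to 46 for lists.

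Among named genes, 3 results reversed: in batch 2 alone pstC stood at -0.008 for 2.57 M against 4.28 M and gvpA at 0.108 for the slope at 2.57 M, where batch 2 lacks M12, and with media matched in KCl share kdpA stood at 0.009, since M1 is then left out. For the genes on the large plasmids, the median reversed or the list test changed direction in several fits. For 2.57 M against 4.28 M the opposite-strand covariate gave -0.075 and ended the call. In batch 1 alone the median was -0.175 for 2.57 M against 4.28 M, 0.191 for the slope at 4.28 M and 0.257 for MgSO4-free media. Without M12 it was -0.085 for the slope at 2.57 M and -0.17 for the difference of slopes, for which the opposite-strand covariate gave 0.154 and 0.178. With culture density it was -0.004 for KCl-free media. Leaving out each culture in turn gave medians of -0.156 to 0.051 for 3.42 M against 4.28 M, -0.361 to 0.454 for the slope at 4.28 M, 0.194 to 0.874 for the difference of slopes, -0.083 to 0.229 for MgSO4-free media and -0.077 to 0.243 for KCl-free media. No named gene of 86 had 50% or fewer of its probes above background on every array of a medium, a measure that the deleted ura3 passed as well, so it does not show that background left their values unchanged.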

Other observations

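The reading of opposite-strand values by gene was chosen after the opposite-strand signal had been seen. The report's comparisons use the strand of each gene, and the same model was fitted to the median of the probes opposite to each of 2128 genes. In MgSO4-free media 51 of these values rose and 14 fell past the test in limma; with the opposite-strand signal of the culture as a covariate 86 rose and 46 fell. Opposite to the regulator gene lrpA1 (VNG1123Gm) the signal rose by 1.55 (SE 0.15, adjusted p = 8.08e-05), where the gene's own strand stood at -0.09. Opposite to hisG (VNG2247G), of histidine synthesis, it rose by 1.10 (SE 0.09, adjusted p = 1.46e-05, gene strand 0.22), and opposite to msrB (VNG1404G), of the repair of oxidised methionine, by 0.82 (gene strand 0.37). Opposite to hisD (VNG1444G) it rose by 0.55 (gene strand -0.21), opposite to phoU (VNG0451G) by 0.33 (gene strand -0.41), and opposite to hsmR (VNG1886a) it changed by -0.46 (gene strand 0.35). Of the genes past the test on both strands, 15 changed in the same direction and 3 in opposite directions. The other comparisons gave 24 higher and 6 lower for the KCl slope at 4.28 M NaCl, 6 and 9 for 2.57 M against 4.28 M, 0 and 5 for 3.42 M against 4.28 M, 5 and 2 for the KCl slope at 2.57 M, 1 and 1 for the slope at 3.42 M, 0 and 2 for the difference of slopes, and 0 and 0 for KCl-free media (limma). With the covariate the slope at 4.28 M gave 39 and 12 and the slope at 2.57 M gave 14 and 2. For 3.42 M against 4.28 M it gave 8 lower.

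Plasmid probes on the opposite strand lay above chromosomal ones by at least 0.14 (log2) in the 9 cultures with an opposite-strand signal over 1.8, and above them by 0.10 in M6 replicate 2; in the other 9 cultures they lay below, at -0.08 to -0.30.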
